A study of Vibrio parahaemolyticus RIMD 2210633 with 16 samples.

How the data were processed

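The series holds 16 arrays of log-phase Vibrio parahaemolyticus grown in alkaline peptone water at 37 °C and then kept for 30 min at 4, 15, 20, 37 or 42 °C, from which total RNA was labelled with Cy3. The arrays were of an Agilent design of 15735 spots, of which 536 were control spots. The remaining 15199 probes, with a median of 3 per gene, covered 4820 genes by locus number, 196 of them with 1 probe. The annotation gave a product for each gene and no gene symbols, and called 1848 genes hypothetical. The arrays lay on 4 slides scanned on 2 days, with the arrays of the first slide scanned on the first day where the day was given.

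The intensity values of 15 arrays were, per the file headers, processed signals of Agilent Feature Extraction 10.5.1.1 with protocol GE1_107_Sep09 for 1 channel, with local background subtracted, spatial trends removed and small values replaced by a surrogate. For replicate 1 at 4 °C the deposited file held the processed signal, the local background and the subtracted signal without spot flags or settings. The authors also deposited log2 values, which had the same distribution on every array and followed the rank order of the processed signal exactly, as quantile normalization makes them. These deposited values were used as an alternative only. No reference genome came with the series, and positions are those of the array's annotation, whose build was not named.

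For the analysis the processed signal was taken to log2 and the 75th percentile of each array was subtracted. Spots called outliers by the scanner software were left out, and a probe was kept when it was well above background on at least 3 of the 15 arrays with that flag. This kept 14000 probes and dropped 1199. The value of a gene was the mean of its probes after each probe was centred over the arrays, and 4581 genes were tested. A single fit of limma 3.58.1 (lmFit and eBayes, R 4.3.3, with data.table in version 1.17.8) with 5 groups and 16 arrays gave 4 comparisons with 37 °C and 3 between the cold temperatures. It had 11 residual degrees of freedom and a prior of 3.25, so 14.3 in total. The p-values were adjusted by Benjamini and Hochberg over the genes of each comparison, a gene was called at an adjusted p under 0.05, and the change of at least 2-fold was an absolute log2 change of at least 1. A gene not well above background on any array of a group was given, as a lower bound, the fold against the lowest level called well above background on each array, or against its own level where that was higher. Brightness was compared with a two-sided exact permutation test. Figures were drawn with matplotlib 3.10.9, numpy 2.4.6, pandas 2.3.3 and python 3.11.15.

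Lists of genes of known pathways, regulators, surface structures and secretion systems were drawn up from knowledge of the species and matched by locus number or product words. Of 43 lists, 41 had at least 5 measured genes and were tested with limma's camera at its preset inter-gene correlation of 0.01, adjusted over all lists and the 4 comparisons with 37 °C together. An estimated correlation and limma's fry, which asks whether the genes of a list move one way on balance, served as alternatives. Counts of members were also adjusted over each list alone. The lists, the fit, the alternatives and the rule for naming genes were chosen before the data were examined, while members found by product words were settled once the annotation was read. The rule named, per comparison with 37 °C, the 10 largest rises and 10 largest falls among called genes whose arrays lay all on one side, up to 4 members of each list with the smallest adjusted p, and a few stress genes fixed in advance, and it named the 5 largest rises and 5 largest falls between cold temperatures. It gave 202, 204, 202 and 199 genes at 4, 15, 20 and 42 °C and 7, 10 and 10 between cold temperatures, of which the text gives a part.

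The alternatives were normexp background correction with an offset of 50 (on the 15 arrays whose files hold the raw signal, so without replicate 1 at 4 °C), quantile normalization, median centring, no filter on dim probes, genes well above background on every array with the flag, the brightest probe of each gene, the authors' log2 values, slide as a fixed block, the replicate number as a block, eBayes with trend and robust options, array weights, the 2 compared groups alone, and each array left out in turn. Fits without replicate 3 at 4 and at 42 °C, and without these and replicate 1 at 37 °C, were chosen after the data were seen. The calculation was tested on simulated data with the observed spread and 100 changed genes per size. Of genes changed by 1 on the log2 scale it called 10, 9, 8 and 5% at 4, 15, 20 and 42 °C, and of those changed by 2 it called 47, 42, 64 and 47%. It also called 3, 2, 6 and 1 unchanged genes. The number of arrays thus limits what can be called, and a gene that did not pass is not shown to be unchanged.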

Results

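Gene expression of the marine bacterium Vibrio parahaemolyticus was measured on 16 single-colour Agilent arrays after 30 min at 4, 15, 20, 37 or 42 °C. There were 3 arrays at each of 4, 15, 20 and 42 °C and 4 arrays at 37 °C, described in the series' design text as biological replicates. The array carried 15199 probes for 4820 genes, of which 3073 lie on chromosome 1 (VP numbers) and 1747 on chromosome 2 (VPA numbers). Each comparison asked which genes respond to a cold or heat stress, with 37 °C as the reference named in the design text. The number of arrays limits the precision of every value given here.

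The mean 75th percentile of the processed signal was 423 ± 118 (SD, n = 3) at 4 °C, 475 ± 125 (SD, n = 3) at 15 °C and 202 ± 29.1 (SD, n = 3) at 20 °C. It was 187 ± 52.9 (SD, n = 4) at 37 °C and 121 ± 23.7 (SD, n = 3) at 42 °C. Relative to 37 °C the signal was 2.26 times as high at 4 °C (two-sided exact permutation p = 0.0571) and 2.54 times at 15 °C (exact p = 0.0286, the smallest this design allows). It did not differ at 20 °C beyond the spread of the arrays (exact p = 0.6) and 0.657 times at 42 °C (exact p = 0.0857). Over these 4 comparisons the Benjamini-Hochberg adjusted exact p-values were 0.114, 0.114, 0.6 and 0.114, so no difference in brightness passed the threshold. The median log2 change of all genes was 0.07, 0.20, 0.08 and -0.01 at 4, 15, 20 and 42 °C. With normexp background correction it was -0.52, -0.52, 0.44 and 0.30, and with median centring 0.04 at 15 °C and -0.11 at 42 °C. On average 86.7% of the probes were well above background at 4 °C, 88.2% at 15 °C, 77.1% at 20 °C, 73.9% at 37 °C and 69.3% at 42 °C.

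Most replicate arrays lay close together, with correlations across genes of 0.961 to 0.982 at 15 °C and 0.972 to 0.982 at 20 °C. Replicate 3 at 4 °C correlated at only 0.770 and 0.755 with the other arrays of its group, and replicate 3 at 42 °C at 0.791 and 0.863. On both of these arrays genes of the capsule, the integron and the pathogenicity island of chromosome 2 were below their level elsewhere. Replicate 1 at 37 °C correlated at 0.950 with replicate 1 at 42 °C and at 0.865 to 0.925 with the other 37 °C arrays. Its median over the 4 genes of the GroES and GroEL chaperonins was 4.22 on the log2 scale against -1.86 to 0.49 on those. These arrays were kept in every comparison, and fits without them are given where they ended the call of a list. The correlation between genes of a list was preset at 0.01, and no list passed at any temperature when it was estimated, as given at each temperature.

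At 4 °C, genes of cold shock proteins, of the polar flagellum and of cyclic di-GMP signalling were higher than at 37 °C. The cold shock regulator CspA encoded by VP1889, a member of a family of small RNA-binding proteins, rose by 4.50 ± 0.92 on the log2 scale (SE, n = 3 and 4), or 22.6-fold (limma adjusted p = 0.0147). Its neighbour VP1888, a hypothetical protein, rose by 4.92 ± 0.82 (30.2-fold, limma adjusted p = 0.00567), and the ribosomal protein L27 gene VP0329 by 2.88 ± 0.32 (7.35-fold, limma adjusted p = 0.00121). The polar flagellar hook-length control gene VP2244 rose by 2.84 ± 0.54 (7.18-fold, limma adjusted p = 0.0102). The GGDEF gene VP0486, of a family that makes cyclic di-GMP, rose by 2.77 ± 0.48 (6.83-fold, limma adjusted p = 0.00603). Lower genes included that of tetrathionate reductase subunit B, VP2011, which fell by 3.25 ± 0.86 (limma adjusted p = 0.0415). Others were formate acetyltransferase VP0994, which fell by 2.49 ± 0.61 (limma adjusted p = 0.0334), and the response regulator TorR, VP1032, which fell by 2.27 ± 0.46 (limma adjusted p = 0.0136). In all of these genes every 4 °C array lay on the same side of every 37 °C array.

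Of the 4 cold shock proteins, 2 rose over all genes tested (3 adjusted over the list alone), VP1889 and the second CspA gene VPA1289 with a log2 change of 3.91 ± 1.03. Of the 59 polar flagellar genes, 9 rose and none fell (19 and 1 adjusted over the list alone), with a median log2 change of 0.70 (camera adjusted p = 0.000122). Within slides 1, 2 and 4, each with 1 array of each group, the medians of the polar flagellum were 1.16, 1.01 and -0.0368. Those of the cold shock proteins were 3.95, 3.92 and 0.39. Slide 1 held replicate 1 at 37 °C and slide 2 held replicate 3 at 4 °C, both in doubt as described above. Only slide 4, where both medians were lowest, held none of the arrays in doubt. With an estimated inter-gene correlation limma's camera passed 0 lists at 4 °C (0 at an unadjusted p under 0.05), and the 14 lists that had passed took adjusted p-values of 0.638 to 0.822. With the directional test fry, 2 lists passed, the polar flagellum and cyclic di-GMP. Of the 26 cyclic di-GMP genes 6 rose and none fell (7 and 1 adjusted over the list alone, median 0.52, camera adjusted p = 0.0347). Of the 17 osmolyte genes, for uptake and synthesis of compatible solutes, 2 rose (3 adjusted over the list alone, median 1.02, camera adjusted p = 0.0204). Of the 36 multidrug efflux genes 3 rose (4 adjusted over the list alone, median 0.60, camera adjusted p = 0.0402). With normexp these last 3 lists had medians of -0.38, -0.25 and -0.48, against -0.52 for all genes. None of them passed then (camera adjusted p = 0.190, 0.199 and 0.852). Cyclic di-GMP did not pass without replicate 2 at 4 °C or 4 at 37 °C, and the osmolytes did not without replicate 1 at 4 °C and had a median of 0.66 without replicate 1 at 37 °C. Efflux did not pass without replicate 1 or 2 at 4 °C, without replicate 1 at 37 °C (median 0.34), or without that array and both replicates 3 at 4 and 42 °C (median 0.26, camera adjusted p = 0.179). Its call was also lost with the stricter background filter (median 0.28), the brightest probe (0.25), array weights (0.32), no filter on dim probes (0.45) and the authors' values (0.55). Single members among them were the BetI regulator VPA1114, at 2.52 ± 0.55, the glycine betaine transporter subunit VP1726, at 1.96 ± 0.48, and the multidrug resistance gene VP0060, at 2.07 ± 0.40 (0.32 with normexp). Of the 14 type II secretion genes 2 rose (5 adjusted over the list alone), VP0138, 3.72-fold, and VP0139, at 2.01 ± 0.42, while the list did not pass (median 0.51, camera adjusted p = 0.0733). It passed without both replicates 3 at 4 and 42 °C (median 0.77, camera adjusted p = 0.000942) and without these and replicate 1 at 37 °C (median 0.70, camera adjusted p = 0.00336). Lists that did not pass with all arrays and did without both replicates 3 were also the 55 ribosomal protein genes (median -0.0680, and -0.52 without the 2 arrays, camera adjusted p = 5.06e-05) and the 11 genes of type VI secretion system 2 (-0.39 and -1.55, camera adjusted p = 0.000594). The others were 24 pili genes (0.29 and 0.64, camera adjusted p = 0.00418) and 10 phage genes (-0.78 and -0.77, camera adjusted p = 0.0329). Without the 3 arrays the aminoacyl-tRNA synthetases passed as well (0.0620 and -0.25, camera adjusted p = 0.0495), and the phage genes did not.

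Lists of energy metabolism had negative medians at 4 °C, of which only glycolysis passed without the 3 arrays in doubt. The medians were -1.46 for the 18 genes of the tricarboxylic acid cycle (camera adjusted p = 0.000777) and -0.82 for 16 glycolytic genes (camera adjusted p = 0.000187). They were -1.19 for 28 genes of anaerobic and nitrate metabolism (camera adjusted p = 0.00228) and -0.56 for 39 genes of respiration and ATP synthase (camera adjusted p = 0.00668). Few members passed on their own, with 0 falls in the tricarboxylic acid cycle and 1 in glycolysis (glucose-6-phosphate isomerase VP2731, at -1.26 ± 0.31). There were 2 in anaerobic metabolism and 0 in respiration, where 1 gene rose, and the counts of falls adjusted over the list alone were 0, 1, 2 and 0. Without both replicates 3 at 4 and 42 °C the tricarboxylic acid cycle had a median of -0.67 (camera adjusted p = 0.0504) and anaerobic metabolism of -0.65 (camera adjusted p = 0.0446). Without these and replicate 1 at 37 °C the medians were -0.16 (camera adjusted p = 0.581) and -0.25 (camera adjusted p = 0.0616), that of respiration was -0.34 (camera adjusted p = 0.0666) and that of glycolysis -0.87 (camera adjusted p = 1.88e-05). Without replicate 1 at 37 °C alone the tricarboxylic acid cycle passed with a median of -0.73. On slide 4, with 1 array of each group, the medians of the tricarboxylic acid cycle and respiration were 0.13 and 0.15. The 14 heat shock chaperones had a median of -1.11 (camera adjusted p = 0.0139) and the 10 proteases of -0.75 (camera adjusted p = 0.0181). The 6 tryptophan synthesis genes had one of -0.85 (camera adjusted p = 0.0488) and the 19 oxidative stress genes of -0.42 (camera adjusted p = 0.0440). In these 4 lists 0, 0, 0 and 2 members fell over all genes tested, and the same numbers adjusted over the list alone. With normexp their medians were -0.88, -0.51, -0.76 and -0.65, against -0.52 for all genes. None of the 4 passed then (camera adjusted p = 0.163, 0.616, 0.121 and 0.152), nor did respiration (camera adjusted p = 0.588). The chaperones did not pass without replicate 1 at 37 °C (median -0.81, camera adjusted p = 0.0587) or without it and both replicates 3 (median -0.63, camera adjusted p = 0.0969), and on slide 4 their median was 0.51. The proteases did not pass without replicate 2 at 4 °C or 4 at 37 °C, and oxidative stress did not without replicate 1 or 2 at 4 °C or 1 or 4 at 37 °C, and had a median of -0.66 without replicate 3 at 4 °C. Tryptophan synthesis did not pass without replicate 3 at 4 °C (median -0.29) or replicate 1 (median -0.49), 2 or 3 at 37 °C, and without the 3 arrays in doubt its median was 0.0584 (camera adjusted p = 0.964). GroEL VP2851 had a log2 change of -2.99 ± 1.03 that did not pass (limma adjusted p = 0.0974).

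The median of the 49 genes of type III secretion system 2 was -1.13 (camera adjusted p = 1.65e-05), and that of 76 integron genes -0.73 (camera adjusted p = 0.000631). Over all genes tested 0 members passed in either list, and 0 adjusted over the list alone. Both shifts rested on replicate 3: without that array the medians were 0.16 and 0.0904. They were -1.73 and -1.24 without replicate 1 at 4 °C, and -1.71 and -1.29 without replicate 2.

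In total 287 genes changed at 4 °C (limma, adjusted p under 0.05 among 4581 genes), 232 higher and 55 lower, and 285 of them changed at least 2-fold. Centring arrays on their median gave 147 higher and 62 lower genes, the stricter background filter 108 and 69, normexp 10 and 1, and slide as a block 116 and 11. Slides 1, 2 and 4 held both groups. Their differences correlated across all genes with the overall changes, of which they are a part, at 0.705, 0.832 and 0.389. Only slide 4, with the lowest correlation, held none of the arrays in doubt. With slide as a block 16 lists passed, 13 of them among the 14. The count was 110 without replicate 1 at 4 °C, 89 without replicate 3 at 4 °C, and 116, 480, 68 and 176 without replicates 1, 2, 3 and 4 at 37 °C. It was 179 without both replicates 3 at 4 and 42 °C and 148 without replicate 1 at 37 °C as well. Limma on these 2 groups alone called 0 genes (753 at an unadjusted p under 0.05). Among the genes named above, the calls of VP1888, VP0329, VP2244, VP0486, VP0060 and VP0138 held with each array left out in turn. VP1889 did not pass without replicate 3 at 4 °C or at 37 °C, VP1032 without replicate 1 at 4 °C, VPA1114 without replicate 3 at 4 or at 37 °C, and VP0139 without replicate 1 at 4 °C or 3 at 37 °C. The calls of VPA1289, VP1726, VP2011, VP0994 and VP2731 were lost without any of 4 to 6 single arrays, replicate 3 at 4 °C and replicates 1 and 3 at 37 °C among them.

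**Figure D1:**
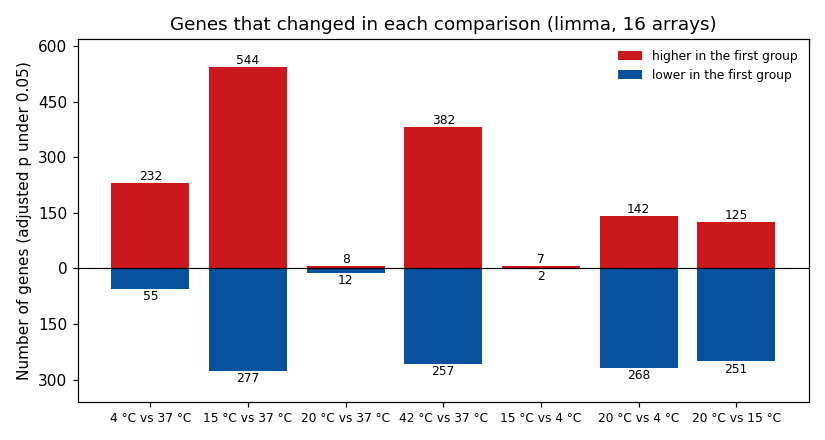
Number of genes higher (red, upward) and lower (blue, downward) in the first group of each of the 7 comparisons, at a limma adjusted p under 0.05 in a fit of 16 arrays. At 15 °C 544 genes were higher and 277 lower, and 9 genes differed between 15 and 4 °C.

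At 15 °C 3 of the 4 cold shock proteins rose (also 3 adjusted over the list alone), and genes of central carbon and energy metabolism fell. VP1890, annotated as a virulence-associated VacB/RNase family protein, rose by 6.64 ± 1.23 on the log2 scale (SE, n = 3 and 4), or 99.8-fold (limma adjusted p = 0.00512). VP1888 rose by 5.83 ± 0.82 (57.0-fold, limma adjusted p = 0.00163) and CspA VP1889 by 4.40 ± 0.92 (21.1-fold, limma adjusted p = 0.00843). These 3 genes lie side by side between positions 1970301 and 1974143 of chromosome 1. The other cold shock genes that rose were VPA1289, by 4.27 ± 1.03, a call lost without replicate 2 at 15 °C, and VPA0552, by 1.35 ± 0.41 (limma adjusted p = 0.0354), a call lost without any single 15 °C array, without replicate 1 or 3 at 37 °C, and with slide as a block, normexp or median centring. The outer membrane protein gene ompK, VP2362, fell by 5.35 ± 0.75 (40.8-fold lower, limma adjusted p = 0.00163). The sugar phosphotransferase gene VPA0230 was 64.0-fold lower and its neighbour VPA0231 fell by 4.87 ± 0.87, and tetrathionate reductase subunit B, VP2011, fell by 4.69 ± 0.86. The sigma factor RpoS, VP2553, which directs transcription under stress and in stationary phase, rose by 2.08 ± 0.41 (limma adjusted p = 0.00687). The gene of the nucleoid protein H-NS, VP1133, fell by 1.85 ± 0.40 (limma adjusted p = 0.00917). In each of these genes every 15 °C array lay on one side of every 37 °C array.

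Of the 18 tricarboxylic acid cycle genes, 10 fell and none rose (12 and 0 adjusted over the list alone), with a median of -2.34 (camera adjusted p = 4.81e-06). With an estimated correlation limma's camera passed 0 lists at 15 °C (2 at an unadjusted p under 0.05), with adjusted p-values of 0.638 to 0.876 in the 16 lists that had passed. All 16 passed without both replicates 3 at 4 and 42 °C, and without these and replicate 1 at 37 °C. Examples of falls were fumarate hydratase VP1873, which fell by 3.07 ± 0.70, and malate dehydrogenase VP0325, which fell by 2.90 ± 0.76. Of 16 glycolytic genes 8 fell (13 adjusted over the list alone, median -1.57, camera adjusted p = 9.68e-08). Among them were phosphoglycerate kinase VP2600, which fell by 1.81 ± 0.38, and fructose-bisphosphate aldolase VP2599, which fell by 1.79 ± 0.34. Of 28 genes of anaerobic and nitrate metabolism 8 fell, as many as adjusted over the list alone (median -1.89, camera adjusted p = 3.22e-06). They included the fumarate reductase subunit genes VP2842 and VP2843, which fell by 3.99 ± 1.01 and by 3.89 ± 0.95, and formate acetyltransferase VP0994, which fell by 3.32 ± 0.61. Of 39 genes of respiration and ATP synthase 13 fell and 3 rose (21 and 7 adjusted over the list alone, median -1.24, camera adjusted p = 5.81e-05). The ATP synthase gamma subunit gene VP3070 was at -1.88 ± 0.39. Of 9 maltose genes 2 fell, as many as adjusted over the list alone (median -2.23, camera adjusted p = 0.000926). The maltose-binding protein gene VPA1401 was at -3.97 ± 0.97, a call lost without replicate 1 at 15 °C, and the median of its list was -1.45 without replicate 3 at 37 °C. The calls were also lost of VP2842 without replicate 2 or 3 at 15 °C, of VP2843 without replicate 2, and of VP0325 without replicate 1 or 2 at 15 °C or 3 at 37 °C.

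Chaperone genes were lower at 15 °C, as 5 of the 14 heat shock chaperones fell and 1 rose (7 and 1 adjusted over the list alone, median -1.70, camera adjusted p = 0.00228). GroEL VP2851 fell by 3.64 ± 1.03, its partner VP2852 by 3.22 ± 0.96 and the second groEL gene VPA0287 by 3.49 ± 1.14. Falls were also seen in the aminoacyl-tRNA synthetases, with 5 of 28 (7 adjusted over the list alone, median -0.62, camera adjusted p = 0.00194). Of the 19 oxidative stress genes 4 fell (5 adjusted over the list alone, median -0.79, camera adjusted p = 0.00805), and of 10 fatty acid oxidation genes 2 fell (2 adjusted over the list alone, median -1.23, camera adjusted p = 0.0194). Of 55 ribosomal protein genes 3 fell (0 adjusted over the list alone, median -0.44, camera adjusted p = 0.000581). Fatty acid synthesis had 3 falls and 1 rise among 19 genes, also adjusted over the list alone (median -0.40, camera adjusted p = 0.0287). The rise was that of VPA0707, a putative delta-9 fatty acid desaturase of the kind that puts double bonds into membrane lipids, by 2.15 ± 0.69. Of 10 proteases 1 fell, also adjusted over the list alone (median -0.67, camera adjusted p = 0.0373). The proteases did not pass without replicate 3 at 15 °C or 4 at 37 °C (median -0.42). Fatty acid synthesis did not without replicate 2 or 3 at 15 °C or 4 at 37 °C (median -0.25) and had a median of -0.60 without replicate 1 at 15 °C. Without replicate 4 at 37 °C the medians of the aminoacyl-tRNA synthetases and ribosomal proteins were -0.39 and -0.26, and without replicate 1 at 37 °C that of fatty acid oxidation was -0.81. The ribosomal proteins did not pass with quantile normalization or the authors' values (medians -0.0384 and -0.0418).

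The lists of the polar flagellum, osmolytes and efflux had positive medians at 15 °C. Of 59 polar flagellar genes 15 rose and none fell (19 and 0 adjusted over the list alone, median 0.57, camera adjusted p = 0.000130), among them flagellin F, VP2261, which rose by 2.32 ± 0.46. Of 17 osmolyte genes 5 rose (10 adjusted over the list alone, median 1.52, camera adjusted p = 0.0108), including the BCCT transporter gene VP1456, by 2.79 ± 0.61, and VP1726, by 2.17 ± 0.48. Of 36 multidrug efflux genes 11 rose and 1 fell, also adjusted over the list alone (median 0.84, camera adjusted p = 0.00753), with VPA0520 at 3.76 ± 0.63. With normexp the osmolyte and efflux medians were -0.29 and -0.27, against -0.52 for all genes, and neither list passed (camera adjusted p = 0.0571 and 0.0569). Of the 49 genes of type III secretion system 2, 1 rose (0 adjusted over the list alone, median 1.05, camera adjusted p = 0.0402). With normexp the median was -0.25 and the list did not pass (camera adjusted p = 0.206). The list did not pass without replicate 1 at 15 °C (median 0.72) or replicate 1 or 4 at 37 °C. Nor did it with the stricter background filter (median 0.42, camera adjusted p = 0.986) or the brightest probe (median 1.04, camera adjusted p = 0.0506). Without both replicates 3 at 4 and 42 °C 25 of the 49 rose (camera adjusted p = 0.000149). The log2 changes themselves were the same, since no array of this comparison was left out. The capsule list did not pass with all arrays (median 1.04, camera adjusted p = 0.0704) and did without those 2 arrays, with 6 of 34 genes higher (camera adjusted p = 0.0164), but not without the 3 arrays in doubt (median 0.74, camera adjusted p = 0.128). Type VI secretion system 2 likewise passed only without the 2 (median -1.07, camera adjusted p = 0.111 with all arrays and 0.0298 without the 2), and did not without the 3 (median -0.94, camera adjusted p = 0.0908). Purine and pyrimidine synthesis passed only without the 3 (medians -0.51 with all arrays and -0.44 without the 3, camera adjusted p = 0.0590 and 0.0258, and 0.0507 without the 2).

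In total 821 genes changed at 15 °C (limma), 544 higher and 277 lower, and 800 of them changed at least 2-fold. Relative to the median change of all genes the medians of the tricarboxylic acid cycle and the polar flagellum were -2.54 and 0.37. The split was 370 higher and 348 lower with median centring, 251 and 285 with the stricter background filter, 85 and 117 with normexp, and 341 and 182 with slide as a block. Differences within the 2 slides holding both groups correlated across all genes with the overall changes at 0.874 and 0.940, and with slide as a block 18 lists passed, the 16 among them. The count was 364, 305 and 385 without replicates 1, 2 and 3 at 15 °C, 383 without replicate 3 at 37 °C and 1486 without both replicates 3 at 4 and 42 °C. The directional test fry passed 6 lists, among them glycolysis, anaerobic metabolism, the polar flagellum, osmolytes and efflux. The calls of VP1888, VP1889, VP1890, VPA0230, VPA0231, VP2362, VP2011, VP0994, VP1873, VP2600, VP2599, VP1133, VP1726 and VPA0520 held under every alternative in which they were tested. There were 20 such alternatives for VP1888, VP1889 and VP1890 and 21 for the others. The calls of VP2553, VP2261, VP1456 and VP3070 were lost only with normexp. Those of the named groES and groEL genes and of VPA0707 were lost without any single 15 °C array, without replicate 3 at 37 °C and with slide as a block. Without replicate 1 at 37 °C, whose groE levels were close to those at 42 °C, VP2852, VPA0287 and VPA0707 lost their calls and VP2851 did not. The named groES and groEL genes also lost theirs with the 2 compared groups alone. The call of VP0325 was also lost with slide as a block and with normexp.

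**Figure D2:**
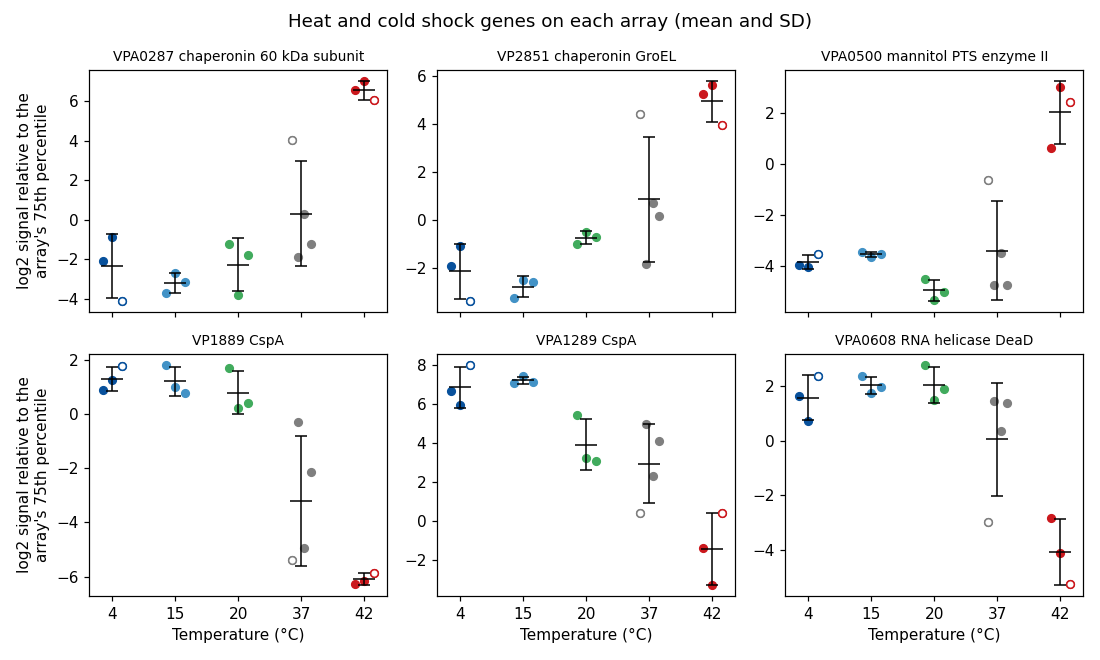
Log2 signal of 6 genes relative to the 75th percentile of each array (vertical axis) at 5 temperatures in °C (horizontal axis), where points are arrays and bars the mean and SD. Open circles are replicate 3 at 4 and 42 °C and replicate 1 at 37 °C; CspA VP1889 lay above every 37 °C array on all arrays at 4, 15 and 20 °C, and VPA0287 was highest at 42 °C with a mean of 6.55.

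At 20 °C few genes differed from 37 °C: 8 were higher and 12 lower. VP1888 rose by 4.94 ± 0.82 on the log2 scale (SE, n = 3 and 4, 30.8-fold, limma adjusted p = 0.0167). GMP reductase VPA1159, of purine salvage, rose by 2.69 ± 0.41 (6.47-fold, limma adjusted p = 0.0149), and ectoine synthase VP1720, which makes a compatible solute, by 1.53 ± 0.30 (2.88-fold, limma adjusted p = 0.0378). The sodium-proton exchanger gene VP2072 rose by 1.77 ± 0.33, and the neighbouring genes of an esterase, VPA0070, and an alcohol dehydrogenase, VPA0071, both rose by 2.13, with SEs of 0.42 and 0.41. The putative protease genes VP2447 and VP2448 fell by 3.99 ± 0.57 and by 2.82 ± 0.49. Peptidase T, VPA1193, fell by 3.51 ± 0.71 and acetate kinase VPA0611 fell by 3.13 ± 0.61. The ferrous iron transporter gene VP0858 fell by 2.52 ± 0.48 and the chemotaxis receptor gene VP2159 fell by 2.83 ± 0.46 (limma adjusted p between 0.0149 and 0.0455). In each of these genes every 20 °C array lay on one side of every 37 °C array, although VPA1193 was well above background on only 1 of 3 arrays and VPA0611 on 2 of 3. The tetrathionate reductase gene VP2009 had a log2 change of -2.48 ± 0.40 (limma adjusted p = 0.0149) with 1 of 3 arrays well above background, and of 0.23 with normexp. None of the other genes named here passed with normexp, and the changes of VP2448, VPA1193, VPA0611 and VP2159 were then -0.16, -0.0756, -0.11 and -0.19.

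The cold shock genes VP1889, at 3.99 ± 0.92, and VPA1289, at 0.96 ± 1.03, did not pass at 20 °C (limma adjusted p = 0.0937 and 0.817). Of the 4 cold shock proteins 0 rose over all genes and 2 rose adjusted over the list alone. Of 28 anaerobic and nitrate genes 0 fell over all genes tested and 8 adjusted over the list alone (median -1.33, camera adjusted p = 5.22e-12). With an estimated correlation limma's camera passed 0 lists at 20 °C (3 at an unadjusted p under 0.05), with adjusted p-values of 0.638 to 0.876 in the 15 that had passed, and with fry anaerobic metabolism and osmolytes did. Glycolysis had 0 of 16 in both counts (median -0.83, camera adjusted p = 5.37e-05). Of 13 genes of branched-chain amino acid synthesis 0 changed over all genes, and 9 rose and 1 fell adjusted over the list alone (median 1.33, camera adjusted p = 5.37e-05). Of 17 osmolyte genes 1 rose, ectoine synthase (3 adjusted over the list alone, median 0.96, camera adjusted p = 3.16e-05). In the 55 ribosomal protein genes 0 changed by either count (median 0.67, camera adjusted p = 9.33e-08, and -0.35 with normexp). Neither did any in tryptophan synthesis (6 genes, median 0.87, camera adjusted p = 0.0194) or type VI secretion system 1 (35 genes, median 0.50, camera adjusted p = 0.0149), nor in the heat shock chaperones (median -0.83, camera adjusted p = 0.0238) or fatty acid synthesis (median 0.29, camera adjusted p = 0.0402, and -0.14 with normexp). The chaperones did not pass without replicate 1 at 37 °C (median -0.22, camera adjusted p = 0.271) or without it and both replicates 3 at 4 and 42 °C (camera adjusted p = 0.179). Fatty acid synthesis did not pass without both replicates 3 (camera adjusted p = 0.0509), without the 3 arrays (median 0.20, camera adjusted p = 0.179), or without replicate 1 or 3 at 20 °C or 1 or 2 at 37 °C. Tryptophan synthesis did not pass without replicate 1 at 20 °C or 2 or 4 at 37 °C (median 0.55 without the last), and type VI secretion system 1 did not with the stricter background filter. The glycolysis median was -0.30 without replicate 1 at 20 °C and that of the osmolytes 0.62 without replicate 1 at 37 °C, and both passed. With normexp the ribosomal proteins and fatty acid synthesis passed in the other direction. Branched-chain and tryptophan synthesis did not pass with it (medians 0.56 and 0.50 against 0.44 for all genes, camera adjusted p = 0.277 and 0.204).

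Type III secretion system 2 had a median of 1.04 at 20 °C (camera adjusted p = 0.000187) with 0 of 49 genes past the threshold in either count. Of these, 4 rose without both replicates 3 at 4 and 42 °C (camera adjusted p = 1.41e-12), with the log2 changes themselves the same. The integron had a median of 0.40 (camera adjusted p = 0.0444) with 0 of 76 genes in either count. Smaller shifts passed for cold-induced RNA and ribosome factors (20 genes, median 0.57, camera adjusted p = 0.0282; 2 rose adjusted over the list alone) and methionine and cysteine synthesis (19 genes, median -0.18, camera adjusted p = 0.00805; 4 fell adjusted over the list alone). They passed also for pili (24 genes, median -0.31, camera adjusted p = 0.00961, and 0.10 with normexp) and cyclic di-GMP (26 genes, median -0.27, camera adjusted p = 0.0238, and 0.42 with normexp). With normexp the median of all genes was 0.44, and neither of these 2 lists passed (camera adjusted p = 0.0602 and 0.950). Cyclic di-GMP did not pass without replicate 2 at 37 °C (median -0.12), nor the pili without that array or replicate 3 at 20 °C (median -0.18), nor the integron without replicate 1 or 2 at 20 °C or 2 or 4 at 37 °C (median 0.24 without the last). The cold-induced factors did not pass without replicate 3 at 20 °C, and without replicate 1 at 37 °C their median was 0.0592 (camera adjusted p = 0.561, and 0.697 without both replicates 3 as well). The median of methionine and cysteine synthesis ranged from -0.37 to -0.11 with 1 array left out, and was lowest without replicate 3 and highest without replicate 1 at 20 °C, and -0.35 without replicate 1 at 37 °C. With the stricter background filter neither type III secretion system 2 nor the integron passed. Lists that passed only with arrays left out were the tricarboxylic acid cycle, oxidative stress and phage genes (medians -0.50, -0.25 and -0.53, camera adjusted p = 0.0470, 0.0456 and 0.0350) without both replicates 3, and the aminoacyl-tRNA synthetases (median -0.34, camera adjusted p = 0.00744) without the 3 arrays. Without the 3 arrays the first 3 of these did not pass (medians 0.19, -0.17 and -0.53, camera adjusted p = 0.912, 0.179 and 0.102), and the tricarboxylic acid cycle changed sign. The synthetases did not pass without both replicates 3 (median -0.16, camera adjusted p = 0.173).

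All 20 genes changed at least 2-fold (limma). The count was 0 with slide as a block (509 at an unadjusted p under 0.05), 0 with normexp (246 unadjusted). It was 0 without any single 20 °C array or without replicate 3 at 37 °C (347 to 387 unadjusted), 13 without replicate 1 at 37 °C, and 115 without both replicates 3 at 4 and 42 °C. The split was 4 higher and 13 lower with median centring, 5 and 12 with quantile normalization and 8 and 8 with the stricter filter. Differences within the 3 slides holding both groups correlated across all genes with the overall changes at 0.732, 0.697 and 0.608, and with slide as a block 16 lists passed, 14 of them among the 15.

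At 42 °C chaperonin genes rose, and cold shock, ribosomal and polar flagellar genes fell. The groES and groEL genes of chromosome 2, VPA0286 and VPA0287, whose products fold other proteins, rose by 6.35 ± 1.07 and by 6.25 ± 1.14 on the log2 scale (SE, n = 3 and 4), or 81.5-fold and 76.0-fold (limma adjusted p = 0.00354 and 0.00600). Those of chromosome 1, VP2852 and VP2851, rose by 4.66 ± 0.96 and by 4.09 ± 1.03. The mannitol phosphotransferase gene VPA0500 rose by 5.42 ± 0.80 (42.8-fold, limma adjusted p = 0.00195) and arginine decarboxylase VPA0170, of polyamine synthesis, by 4.53 ± 0.81 (23.1-fold, limma adjusted p = 0.00513). CspA VPA1289 fell by 4.37 ± 1.03 (20.6-fold lower, limma adjusted p = 0.0170). The RNA helicase gene deaD, VPA0608, fell by 4.12 ± 0.89 (17.4-fold lower, limma adjusted p = 0.0125). The fructose phosphotransferase gene VPA1424 and its neighbour VPA1425, for mannose-6-phosphate isomerase, were 39.4-fold and 40.4-fold lower, each well above background on 1 of 3 arrays at 42 °C.

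All 4 of the 14 heat shock chaperones that rose were groES and groEL genes (also 4 adjusted over the list alone, median 1.45, camera adjusted p = 0.00482). With an estimated correlation limma's camera passed 0 lists at 42 °C (1 at an unadjusted p under 0.05), with adjusted p-values of 0.638 to 0.822 in the 16 lists that had passed. DnaK VP0653, at 1.51 ± 0.65, HtpG VP0821, at 1.79 ± 1.02, and the heat shock sigma factor gene VP2953, at 1.31 ± 0.43, did not pass (limma adjusted p = 0.127, 0.244 and 0.0568). Replicate 1 at 37 °C had groE levels close to those at 42 °C, and without it and both replicates 3 at 4 and 42 °C the list had 10 rises (median 2.89, camera adjusted p = 2.94e-05), with a median of 2.25 without replicate 3 at 42 °C alone. The envelope stress genes VP2857 (CpxP) and VP2858 (CpxR) rose by 2.22 ± 0.43 and by 1.37 ± 0.31. Of the 12 envelope stress genes 2 rose and 1 fell (3 and 1 adjusted over the list alone) and the list did not pass (median -0.55, camera adjusted p = 0.917). Of 19 oxidative stress genes 3 rose and 1 fell (6 and 1 adjusted over the list alone, median 0.69, camera adjusted p = 0.0204). The list did not pass without the 3 arrays (median 0.93, camera adjusted p = 0.0581), and its median was 1.06 without replicate 1 at 42 °C. The rises were those of the Dps protein VPA0563, which protects DNA, by 3.19 ± 0.64, and of the catalase-peroxidases VPA0453 and VPA0768, by 3.01 ± 0.57 and by 2.79 ± 0.60.

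Of 55 ribosomal protein genes 23 fell and none rose (43 and 0 adjusted over the list alone, median -1.25, camera adjusted p = 1.70e-15). The genes of L27, VP0329, and S7, VP2772, were at -1.69 ± 0.32 and -1.71 ± 0.40. Of 20 cold-induced RNA and ribosome factors 8 fell (13 adjusted over the list alone, median -1.28, camera adjusted p = 5.55e-06). Among them were the RNA helicases RhlE, VPA0390, at -2.78 ± 0.63 and DbpA, VP0288, at -2.21 ± 0.50. Of the 4 cold shock proteins 2 fell (3 adjusted over the list alone). VP1889 was not well above background on any 42 °C array, at least 2.25-fold lower and short of the threshold (limma adjusted p = 0.0505).

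The flagellar systems moved apart at 42 °C. Of 59 polar flagellar genes, of the swimming organelle, 13 fell and none rose (16 and 0 adjusted over the list alone, median -0.36, camera adjusted p = 3.16e-05, and -0.54 without replicate 1 at 37 °C). Of 39 lateral flagellar genes, of the swarming organelle, 14 rose and 1 fell (20 and 1 adjusted over the list alone, median 0.93, camera adjusted p = 7.56e-07). The polar flagellin genes VP2259 and VP0790 fell by 2.77 ± 0.31 and by 2.74 ± 0.33 (limma adjusted p = 0.000561 and 0.000624). Flagellin F, VP2261, not well above background on any 42 °C array, was at least 3.38-fold lower. The lateral capping protein gene VPA1550, not well above background on any 37 °C array, was at least 2.23-fold higher (limma adjusted p = 0.000672), and the lateral motor switch gene VPA1541 rose by 2.54 ± 0.42. OpaR, VP2516, the regulator of colony opacity and capsule, fell by 2.14 ± 0.46 (limma adjusted p = 0.0126). The quorum sensing list, to which it belongs, had 3 rises and 2 falls among 10 genes (4 and 4 adjusted over the list alone, median -0.29, camera adjusted p = 0.930).

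Branched-chain amino acid synthesis rose at 42 °C, with 8 of 13 genes (9 adjusted over the list alone, median 2.02, camera adjusted p = 8.31e-05), such as 2-isopropylmalate synthase VP0346, by 2.19 ± 0.43. The median was 1.24 without replicate 3 at 42 °C. Of 43 genes of type III secretion system 1, 4 rose (2 adjusted over the list alone, median 0.98, camera adjusted p = 5.92e-05). Among them was the chaperone gene VP1687, not well above background on any 37 °C array and at least 3.42-fold higher. The 18 tricarboxylic acid cycle genes had a median of 0.95 (camera adjusted p = 0.0324) with 0 members past the threshold in either count. The 16 glycolytic genes had one of -0.83 (camera adjusted p = 0.0482) with 3 falls and 1 rise (4 and 2 adjusted over the list alone). Of 5 chitin genes 1 rose (2 adjusted over the list alone, median 1.50, camera adjusted p = 0.0379). The 14 type II secretion genes had a median of -0.56 (camera adjusted p = 0.0288) with 0 in either count. Glycolysis, chitin and type II secretion did not pass without replicate 3 at 42 °C, where the medians were -0.51, 0.97 and -0.42, and glycolysis and chitin did not without both replicates 3 (camera adjusted p = 0.235 and 0.107) or without the 3 arrays (0.145 and 0.103). Chitin and type II secretion also did not pass without replicate 2 at 42 °C, nor glycolysis without replicate 1 at 42 °C or 3 or 4 at 37 °C. The tricarboxylic acid cycle did not without replicate 2 or 3 at 42 °C, replicate 2 or 4 at 37 °C (median 0.56 without the last) or both replicates 3 (camera adjusted p = 0.0684), and had a median of 1.55 without replicate 1 at 37 °C. Of 10 vibrioferrin genes, for synthesis and uptake of the siderophore, 2 fell (4 adjusted over the list alone, median -1.28, camera adjusted p = 0.0193). Of 17 other iron uptake genes 1 fell (1 adjusted over the list alone, median -0.80, camera adjusted p = 0.0140). With normexp these medians were 0.21 and 0.01, against 0.30 for all genes, and neither list passed (camera adjusted p = 0.950 and 0.205). Vibrioferrin also did not pass without replicate 4 at 37 °C (camera adjusted p = 0.0554). The other iron uptake genes did not with the stricter background filter (median -0.47, camera adjusted p = 0.348).

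Of 34 capsule genes 3 fell at 42 °C, also adjusted over the list alone (median -2.01, camera adjusted p = 0.000104). Without both replicates 3 at 4 and 42 °C, on which capsule genes lay below their level elsewhere, 10 fell (median -1.08, camera adjusted p = 2.45e-06). Type III secretion system 2 had a median of -0.52 (camera adjusted p = 0.304; 0 of 49 genes in either count) with all arrays and of 0.47 (camera adjusted p = 0.00638) without those 2, and it did not pass without the 3 arrays (median 0.38, camera adjusted p = 0.145). The integron, at -0.21, and type VI secretion system 2, at 1.87, moved to 0.51 and 0.88 without the same arrays. Only the second had passed with all arrays (camera adjusted p = 0.917 and 0.0288, and 0.000942 and 0.256 without those arrays), and it did not pass without replicate 1 at 37 °C and had a median of 2.87 without replicate 1 at 42 °C. Of their 76 and 11 genes 3 and 0 rose (0 and 0 adjusted over the list alone). Type VI secretion system 1 passed only without those 2 arrays (median 0.62, camera adjusted p = 0.00298) or the 3 arrays (median 0.61, camera adjusted p = 0.0394).

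In total 639 genes changed at 42 °C (limma), 382 higher and 257 lower, and 622 of them changed at least 2-fold. The count was 172 and 279 without replicates 2 and 3 at 42 °C and 268 and 309 without replicates 2 and 3 at 37 °C. Without replicate 4 at 37 °C 161 genes were higher and 76 lower. It was 1254 without replicate 1 at 37 °C and 1666 without that array and both replicates 3. It was 24 with limma on these 2 groups alone and 21 with normexp (19 higher, 2 lower), where the changes of VP2516, VP2261 and VP0288 were -0.0249, -0.19 and -0.30. With slide as a block it was 546, with 17 lists passed, the 16 among them. Differences within the 3 slides holding both groups correlated across all genes with the overall changes at 0.711, 0.883 and 0.870. With the directional test fry 6 lists passed, the heat shock chaperones, ribosomal proteins, branched-chain synthesis, both flagellar lists and oxidative stress. The calls of VPA0286, VPA0287, VP2852, VPA0500, VPA0170, VP2259, VP0790, VP2261, VP2516, VP0329, VPA0563, VPA0453, VPA1550, VPA1541, VP2857 and VP0346 held with each array left out in turn. Those of VPA0608 and VPA0768 were lost without replicate 3 at 42 °C, that of VP2858 without replicate 2, and those of VPA1424, VPA1425, VPA0390 and VP0288 without either. That of VPA1289 was lost without replicate 2 at 42 °C or 2 or 4 at 37 °C, and that of VP2772 without replicate 3 at 42 °C or 4 at 37 °C. Those of VP2851 and VP1687 were lost without replicate 2 at 42 °C or without replicate 2, 3 or 4 at 37 °C.

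**Figure D3:**
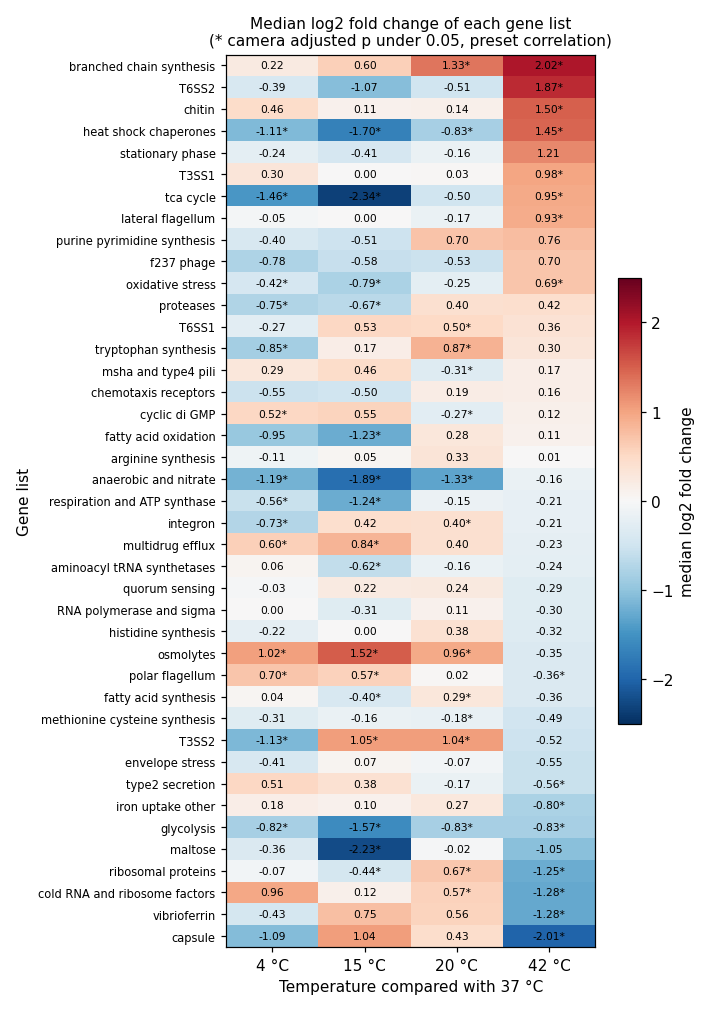
Median log2 fold change against 37 °C of the members of 41 gene lists (vertical axis) at 4 temperatures (horizontal axis), with a star where the camera adjusted p with the preset correlation was under 0.05. Heat shock chaperones had medians of -1.11, -1.70 and -0.83 at 4, 15 and 20 °C and of 1.45 at 42 °C.

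The cold temperatures were also set against each other. Between 15 and 4 °C only 9 genes differed (limma, 7 higher and 2 lower). The gene of ribosomal protein L27, VP0329, was 4.01-fold lower at 15 °C and the efflux gene VPA0168 higher by 2.68 ± 0.44 (SE, n = 3 and 3, limma adjusted p = 0.0326 and 0.0290). Between 20 and 4 °C 410 genes differed, 142 higher and 268 lower at 20 °C. The ribose transporter gene VPA1087 was higher at 20 °C by 5.52 ± 1.54 and the nucleoside transporter gene VP2437 by 3.71 ± 0.91. The pyruvate formate lyase activating enzyme gene VP1381 was lower, at -3.94 ± 0.69 (limma adjusted p = 0.0419, 0.0246 and 0.00482 in turn). Between 20 and 15 °C 376 genes differed, 125 higher and 251 lower at 20 °C. The gene ompK, VP2362, was higher by 6.07 ± 0.80, VPA1087 higher by 7.01 ± 1.54 and adenylate cyclase VP2987 lower, at -3.47 ± 0.64 (limma adjusted p = 0.00204, 0.0170 and 0.00809). The hypothetical protein gene VPA1291, not well above background on any 20 °C array, was at least 23.1-fold lower at 20 than at 4 °C and at least 6.94-fold lower than at 15 °C, with a log2 change of 0.50 in the second comparison with normexp.

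With slide as a block these 3 counts were 2, 189 and 63, and with the replicate number as a block 3, 342 and 339. Between 15 and 4 °C limma called 4, 1 and 4 genes without replicates 1, 2 and 3 at 4 °C and 0 without any 15 °C array (457 to 460 at an unadjusted p under 0.05). Between 20 and 4 °C the counts were 261, 410 and 211 without replicates 1, 2 and 3 at 4 °C and 154, 141 and 99 without those at 20 °C. Between 20 and 15 °C they were 153, 99 and 116 without those at 15 °C and 175, 105 and 72 without those at 20 °C. With normexp 811 genes were higher and 112 lower at 20 than at 4 °C and 1764 and 164 at 20 than at 15 °C. The stricter background filter gave 157 and 163, and 144 and 122, and quantile normalization gave 8 and 7 between 15 and 4 °C. The calls of VP1381, VP2362 and VP2987 held with each array left out, and those of VP0329, VPA0168, VPA1087 and VP2437 did not. That of VPA1291 held between 20 and 4 °C and was lost between 20 and 15 °C without any of the 6 arrays. With slide as a block, where 20 and 15 °C share only slide 1, the calls of VP2987, VPA1087 and VPA1291 between these temperatures were lost, as were those of VP0329 and VPA0168 between 15 and 4 °C.

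The responses were also compared as a whole. The log2 changes at 4 and 15 °C correlated at 0.665 across genes, which are not independent replicates, against 0.428 in 100 simulations of unchanged groups that share the 37 °C arrays, and the covariance was 0.859 against 0.191. Of the called genes 144 were higher at both temperatures and 33 lower at both, and 0 went opposite ways. Independent lists would share 27.6 and 3.33. Simulated unchanged groups shared 0 and 0, but few genes are called where none changed. Such simulated counts, here and in the other pairs, are thus no yardstick for the shared calls. When each comparison used 2 of the 4 control arrays, over the 6 ways to choose them, the correlation was 0.486 on average (0.403 to 0.549) and 25 and 2.33 genes were shared. Between 15 and 42 °C the correlation was -0.253 (-0.283 with split controls, covariance -0.380 against 0.191). In this pair 84 called genes went opposite ways against 21 higher and 12 lower in both (53.6, 45.4 and 15.5 for independent lists, and 84.2, 3.17 and 2.33 with split controls).

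**Figure D4:**
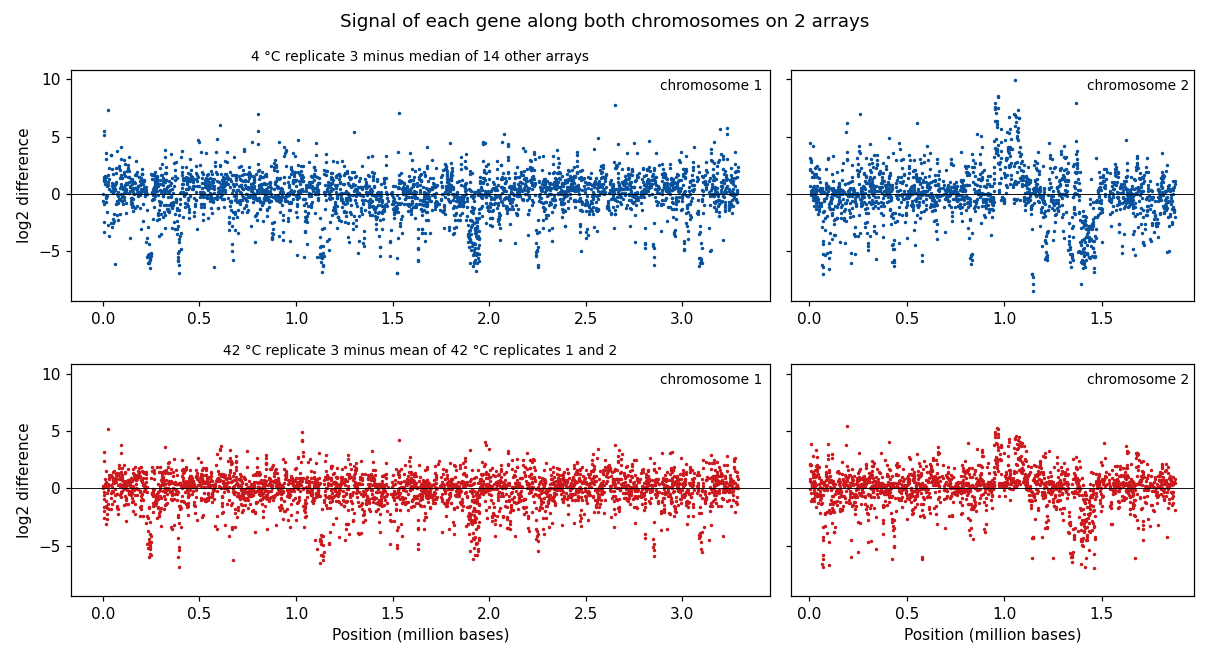
Log2 difference of each gene along chromosomes 1 and 2 (position in Mb as the array's annotation gives it, build not named) on replicate 3 at 4 °C, against the median of 14 other arrays, and on replicate 3 at 42 °C, against the mean of the other 42 °C arrays. Points far below 0 fall in the same stretches on both arrays, such as the capsule genes VP0216 to VP0236 with medians of -5.37 and -4.28. The log2 changes at 4 and 20 °C correlated at 0.216 (0.429 in simulated unchanged groups, 0.0101 with split controls) and those at 15 and 20 °C at 0.449 (0.429 and 0.229), and neither correlation exceeded the highest simulated ones, 0.468 and 0.482. The covariances were 0.174 and 0.409, against 0.192 and 0.193 in the simulations, so that at 15 and 20 °C lay above its simulated mean. At 15 and 20 °C 6 called genes were higher and 9 lower in both, and 0 went opposite ways. Simulated groups shared 0 and 0 on average, independent lists would share 0.950 and 0.726, and 1.17 and 0.833 were shared with split controls. At 4 and 20 °C 2 were higher and 5 lower in both and 1 went opposite ways (0 and 0.01 shared in simulated groups, 0.405 and 0.144 for independent lists, 0.333 and 0 with split controls). The changes at 42 °C correlated at -0.0444 with those at 4 °C and at -0.182 with those at 20 °C (-0.0889 and -0.261 with split controls). Of the called genes 33 went opposite ways at 4 and 42 °C against 2 higher and 3 lower in both, and 1 against 0 and 3 at 20 and 42 °C. Independent lists would give 17.6, 19.3 and 3.09 in the first pair and 1.45, 0.667 and 0.673 in the second. With split controls the numbers were 58.3, 0.833 and 0.167, and 5.33, 0 and 0.167. Simulated unchanged groups correlated at 0.429 and 0.430 in these pairs.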

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

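The tests of the patterns weighed here and of other splits of the arrays were chosen only after the results were seen. Among the 37 °C arrays, 149 values of named genes, list medians and array brightness were searched for an array far from the other 3, where chance would give 7.45 such values, and 2 were found, both on replicate 1 at 37 °C. On that array CpxR, VP2858, had a log2 level of 1.00 against 0.02 to 0.13 on the others. GMP reductase, VPA1159, had a level of -3.31 against -2.01 to -1.76.

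Replicate 1 at 37 °C resembled the 42 °C arrays. Its difference from the other 37 °C arrays had a mean slope of 0.641 along the difference between 42 °C and the remaining 37 °C arrays. An exchange of labels with a 42 °C array was argued against, since the lowest 42 °C array lay 4.53 log2 units above the highest of the other 37 °C arrays in the 4 groES and groEL genes, so no partner was out of place. An effect of its slide and scan day was argued against, since the arrays at 4, 15 and 20 °C on that slide had slopes of at most 0.0498 along the same difference. A warmer culture or a single wrong label may explain it, and the values do not tell these apart. Its median over the groES and groEL genes, 4.22, lay below those of the 42 °C arrays, 5.03 to 6.33. Yet it correlated at 0.950 with replicate 1 at 42 °C, as replicates 1 and 2 at 42 °C did with each other.

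On replicate 3 at 4 °C genes in 28 stretches of the chromosomes were lower than on other arrays, and 25 of these stretches were also lower on replicate 3 at 42 °C. Another 11 stretches were higher on the 4 °C array, and 5 of them were also higher on the 42 °C array. The 4 °C array was set against arrays of all temperatures, so genes raised by cold can be among the 11. One such stretch, VPA1289 to VPA1296, holds a cold shock protein. Over VPA0916 to VPA1027, where others of the 11 lie, the median log2 level was -7.94 and -8.69 on 4 °C replicates 1 and 2. On replicates 3 at 4 and 42 °C it was -3.72 and -4.68, which argues against cold for these stretches. The count alone cannot show whether both arrays held the same strain, which is left open. Of the 264 low genes 40.5% lay in runs of at least 4 neighbours, where 1000 shuffled orders gave at most 1.89%. This argues against poor hybridisation or labelling that struck genes at random. Shuffling also breaks up operons and islands, so a loss that follows them is not covered. The incubation temperature was argued against, because the other 4 °C arrays differed from 37 °C by a median of 0.0927 over the same genes. RNA from a strain of other gene content may explain the pattern, since 84.1% of the genes low on the 4 °C array were also at least 2 log2 units lower on the 42 °C array, against 5.38% of 4551 other genes. Some low genes, 57.2%, were still called well above background, and no genome was at hand to test the hypothesis further.

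More called genes were higher than lower at 4, 15 and 42 °C. With only genes well above background on every array with the flag, 46.8% of the calls at 15 °C were higher, in place of 66.3%. This does not show a signal floor on the dimmer 37 °C arrays to be the cause. In the 112 genes VPA0916 to VPA1027, mostly near background at both temperatures, median log2 levels were -8.51 to -7.73 at 15 °C. At 37 °C they were -7.51 to -5.97, so genes near a floor would read lower at 15 °C, not higher. At 4 °C the share was 61.0% in place of 80.8%, and a floor was likewise not shown to be the cause. At 42 °C, where the arrays were 0.657 times as bright as at 37 °C, 59.8% of the calls were higher, and 58.9% with that filter. A floor on these dimmer arrays would act toward higher values, yet the filter hardly moved the share. That filter also drops genes that are silent at 37 °C for any other reason, and no biological explanation was tested. Centring on the median shifts all changes alike and so moves the share by construction. The share moved toward even at 4, 15 and 42 °C and away from it at 20 °C (from 40 to 23.5%). Median centring was not used as a test of the scaling.

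Of the 35 splits of the 7 arrays at 4 and 37 °C, 2 gave as many called genes as the real one, 287 against a highest other count of 328, and 2 as many changed at least 2-fold, 285 against 325, so chance could not be excluded. The highest other split put replicate 2 at 37 °C with the 4 °C arrays. At 15 °C only the real split, 1 of 35, gave 821 genes (highest other 544) and 800 at least 2-fold (536). At 20 °C 1 of 35 gave 20 genes (5) and 20 at least 2-fold (5). For these fits without slide that share is the smallest that 35 splits allow, and it was not adjusted over the temperatures. Chance was thus not excluded at either temperature. With slide as a block limma called 523 genes at 15 °C and 0 at 20 °C (509 at an unadjusted p under 0.05), and 0 at 20 °C without any single 20 °C array, so the count at 20 °C does not hold across fits. At 42 °C 2 of 35 splits gave as many, 639 genes against 1173 and 622 at least 2-fold against 1095, so chance could not be excluded. There the highest other split put replicate 1 at 37 °C with the 42 °C arrays, which points to the structure described above. For the lists 19, 6, 10 and 11 of 35 splits at 4, 15, 20 and 42 °C gave as many, with 14, 16, 15 and 16 lists against 21, 19, 19 and 20 in the highest other split, so chance could not be excluded for the number of lists. The cold temperatures had 10 splits each, too few for a share under 0.05, with 9 genes between 15 and 4 °C against 4 in the highest other split, 410 against 1 between 20 and 4 °C and 376 against 0 between 20 and 15 °C, and 1 split, the real one, as large in each.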

How the results depend on the processing

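The fits without 2 or 3 arrays were chosen only after the results were seen, and the other alternatives were planned. Among the counts of genes and lists, 133 values under the other alternatives stayed within 1.5 times the reported count, 49 were lower and 32 higher, and with 1 array left out 43 stayed, 55 were lower and 4 higher. Among medians of lists 2116 and 1038 kept direction and side of the threshold, 224 and 57 were no longer past it, 88 and 50 came past it, and 16 and 3 changed direction. Among named genes 1501 and 628 kept both, 306 and 280 lost their call, 19 and 8 gained one, and 2 and 0 changed direction. The cause was not tested for any change given here, except that fewer arrays or fewer genes tested act by construction. Leaving out both replicates 3 at 4 and 42 °C takes no array from the comparisons of 15 and 20 °C with 37 °C. The log2 changes there stayed the same. The counts rose from 821 to 1486 and from 20 to 115 through the estimate of the spread in the joint fit.

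With normexp background correction limma called 11 genes at 4 °C, 202 at 15 °C, 0 at 20 °C (246 at an unadjusted p under 0.05) and 21 at 42 °C, and the same numbers at least 2-fold. It called 2 genes between 15 and 4 °C, 923 between 20 and 4 °C and 1928 between 20 and 15 °C. It used the 15 arrays with raw signals, without replicate 1 at 4 °C, and its offset of 50 lies within the range of the arrays' median signals, 20.1 to 118. With the stricter background filter 177 genes (174 at least 2-fold) were called at 4 °C, 536 (514) at 15 °C and 24 between 15 and 4 °C, and with the brightest probe 163 (163) at 4 °C. Between 15 and 4 °C quantile normalization gave 15 genes and the authors' log2 values 17.

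With slide as a block limma called 127 genes (127 at least 2-fold) at 4 °C, 523 (522) at 15 °C and 0 (0) at 20 °C, where 509 had an unadjusted p under 0.05. It called 2 genes between 15 and 4 °C, 189 between 20 and 4 °C and 63 between 20 and 15 °C. Array weights gave 748 (603), 2286 (1634), 491 (364) and 1190 (1133) genes at 4, 15, 20 and 42 °C, and 625, 1358 and 2218 between 15 and 4, 20 and 4, and 20 and 15 °C. The weights were lowest for replicate 3 at 4 °C, 0.116, and replicate 3 at 42 °C, 0.181, and their estimation stopped before it converged. Limma on the 2 compared groups alone called 0 (0) genes at 4 °C (753 unadjusted), 24 (24) at 42 °C, 0 between 15 and 4 °C (562 unadjusted), 47 between 20 and 4 °C and 1575 between 20 and 15 °C.

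With a replicate block limma called 112 genes (112 at least 2-fold) at 4 °C, 5 (5) at 20 °C, 171 (171) at 42 °C and 3 between 15 and 4 °C. Arrays of the same number had correlations of their deviations between -0.208 and 0.680, with 13 of 30 pairs above 0.1, against 11 of 72 pairs of different number, and for 11 of the 16 arrays the closest array had the same number. Of the pairs of the same number on different slides 6 of 14 lay above 0.1, and of those of different number on the same slide 3 of 8. A pairing by number is thus not excluded. No block was stated with the series and the main fit used none, so its p-values do not allow for a pairing.

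Without both replicates 3 at 4 and 42 °C 179 genes (179 at least 2-fold) were called at 4 °C, 1486 (1287) at 15 °C, 115 (115) at 20 °C, 23 between 15 and 4 °C and 973 between 20 and 15 °C. Without these and replicate 1 at 37 °C the counts were 148 (148), 1489 (1239), 173 (158) and 1666 (1477) at 4, 15, 20 and 42 °C, and 133, 895 and 1377 between 15 and 4, 20 and 4, and 20 and 15 °C. With 1 array left out they ranged from 68 to 480 (68 to 477 at least 2-fold) at 4 °C, from 305 to 916 (305 to 903) at 15 °C, from 0 to 29 (0 to 29) at 20 °C and from 172 to 1254 (172 to 1185) at 42 °C. Between 15 and 4 °C they ranged from 0 to 4, between 20 and 4 °C from 99 to 410 and between 20 and 15 °C from 72 to 175. A count of 0 came with limma without any 15 °C array between 15 and 4 °C (457 to 460 unadjusted) and without any 20 °C array or replicate 3 at 37 °C at 20 °C (347 to 387 unadjusted).

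The lists that passed numbered 12 to 16 at 4 °C, 14 to 17 at 15 °C, 13 to 18 at 20 °C and 13 to 17 at 42 °C with 1 array left out. With an estimated correlation limma's camera passed 0, 0, 0 and 0 lists (0, 2, 3 and 1 at an unadjusted p under 0.05) at 4, 15, 20 and 42 °C, and fry passed 2, 6, 2 and 6.

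Some lists changed direction relative to the other genes, most of them also in the sign of their median. With normexp the medians were 0.21 for ribosomal proteins, 0.18 for purine and pyrimidine synthesis and -0.79 for type III secretion system 1 at 4 °C, and -0.26 for ribosomal proteins at 15 °C, where the sign of the median (-0.44 as reported) did not change. At 20 °C they were -0.35 for ribosomal proteins, -0.14 for fatty acid synthesis, -0.27 for the polar flagellum and 0.61 for type III secretion system 1 (0.0271 as reported). The integron had medians at 4 °C of 0.0501 with array weights, 0.0904 without both replicates 3 and 0.23 without 3 arrays, and at 42 °C of 0.51 and 0.58 in the last pair. Type III secretion system 2 had a median of 0.47 at 42 °C without both replicates 3. Without 3 arrays the aminoacyl-tRNA synthetases had -0.25 and tryptophan synthesis 0.0584 at 4 °C. With 1 array left out the medians ranged from -1.73 to 0.16 for type III secretion system 2 at 4 °C, from -1.29 to 0.0904 for the integron at 4 °C and from -0.72 to 0.51 for the integron at 42 °C, each highest without replicate 3. With normexp VP2009 had a change of 0.23 at 20 °C and VPA1291 one of 0.50 between 20 and 15 °C.

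Signal over background limited the dim genes, since 69.3% of the probes were well above background at 42 °C against 88.2% at 15 °C, and a fold of a gene not above background in a group is a lower bound.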

Other observations

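The values here belong to no comparison, and they were looked up only after the results were seen. In the 112 genes VPA0916 to VPA1027, from position 949336 to 1082023 of chromosome 2, 80.4% of the genes were well above background on replicate 3 at 4 °C. The share was 51.8% on replicate 3 at 42 °C, 43.8% on replicate 2 at 42 °C and 26.8% on replicate 4 at 37 °C, and 2.68 to 9.82% on the other arrays with the flag. Replicate 2 at 42 °C and replicate 4 at 37 °C stayed in the fits without 2 or 3 arrays. Those fits are thus not shown to be free of this pattern. Replicate 2 at 42 °C was also part of the level against which replicate 3 at 42 °C was set. The median log2 level of replicate 4 at 37 °C was -6.77, within the range of the other 37 °C arrays, -7.51 to -5.97. In the 87 genes VPA1310 to VPA1396, which hold type III secretion system 2 and the thermostable direct hemolysin genes, 18.4% were well above background on replicate 3 at 4 °C and 12.6% on replicate 3 at 42 °C, against 96.6% on replicate 2 at 4 °C.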
